A study of Mus musculus with 3 samples.

How the data were processed

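RNA from B16 mouse melanoma cells with a stably integrated empty vector was sequenced in 3 samples, which the labels name as numbered Mock replicates of one line. Total RNA was purified on NucleoSpin columns and the sequencing provider (BGI) made the libraries by its standard eukaryotic procedure, per the labels' protocols. The genome build was GRCm38.p6, per the submitters' processing notes. The aligner, the counting tool, the gene annotation, any filters and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies, can therefore be assigned to either partner. Levels of genes with fractional counts are uncertain to that extent. Among the genes named in the report these are St3gal1, Neu3, Asah1, Ctsa, Bace1, Tyr, H2-D1, Tapbp, Ccnd1, Nphs1, Hba-a1, Actb, Gapdh, Tuba1b, Ftl1, Eno1, Gm39701, Gm40498 and the 5 genes of widest range, and in the other parts also H2-T10, Oas1a, Hspa1a, Hspa1b, H2-T22, Ifnar1 and Itgb1. Enrichment of polyadenylated RNA or removal of ribosomal RNA is likewise not given in the sources used here.

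The authors' deposited table gives estimated counts of reads per gene symbol, 1 column per sample, without normalization and without pooling of samples. It holds 17285 rows. In 2270 of them (13.1%) a value differed from a whole number by more than 0.005 in at least 1 sample, as happens when reads that match several genes are divided among them. Counts were rounded to whole numbers before every test, which left 2877 rows with no count and 14408 to test. The symbol Plin2 stands on 2 rows, and 11 rows are named by a bare number. RefSeq or Ensembl names matched 17124 symbols, and 16648 are protein coding by RefSeq. Positions and exon lengths came from the GENCODE M21 annotation of GRCm38 by symbol, for the 16842 symbols with 1 gene there, and exon length is that of all annotated exons merged. The sharing of sequence between genes was counted in words of 31 bases over all GENCODE M21 transcripts, for 5 class I pathway genes. The table holds 0 mitochondrially encoded genes and 0 of 16 genes listed to judge RNA selection (mitochondrial and nuclear noncoding RNAs), so RNA selection and mitochondrial content were not analysed here. CPM values refer to the genes of the table alone.

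Totals were 9328096, 9456527 and 9438905 counts in replicates 1, 2 and 3, a highest to lowest ratio of 1.014. They were scaled by TMM factors of 1.0034, 0.9977 and 0.9989. At this depth a gene at 1 CPM is expected to collect 28.2 reads over the 3 libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

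The lists, the design of each test and most alternatives were fixed before the data were examined. The 19 lists hold 261 genes. Each gene's level was tested against 1 CPM with edgeR 4.0.16 in R 4.3.3, as the quasi-likelihood F statistic of an intercept-only model whose offsets make an intercept of 0 equal to 1 CPM, two-sided, with Benjamini-Hochberg adjustment over all genes with at least 1 count. The test function of edgeR does not take a design of 1 column, so the same statistic was computed from its fit: the difference in deviance divided by the posterior quasi-dispersion, bounded by the Poisson likelihood ratio test. Genes with an adjusted p under 0.05 were called above or below, others unresolved. Ratios to St3gal5 were formed within each library from counts plus 0.5 and tested with limma 3.58.1 with a mean-variance trend. Variation between libraries was tested gene by gene with a Poisson deviance test (chi-square, 2 degrees of freedom) for means of at least 10 counts. The biological coefficient of variation is edgeR's common value. Each list's median of log2(CPM + 1) was placed among 10000 random lists of the same size drawn from the table, as a description without a p-value. Exact binomial (Clopper-Pearson) intervals of reads relative to St3gal5 were computed in R 4.3.3. The other intervals and the permutation tests used scipy 1.17.1, and plots used matplotlib 3.10.9.

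Genes were named by a rule set before the data were examined: all sialyltransferase and ganglioside synthesis genes, in each other list the 4 with the highest mean CPM and those with no count, the 20 most abundant genes, and the 5 widest and 5 narrowest log2 ranges among varying genes with a mean of at least 100 counts. One gene that this rule names is not reported here. Other genes were named after their values were seen, where they make up a count of 5 or fewer or are singled out in the text. Of the listed genes, some had no row under their symbol and were not analysed here, among them St6gal2, St6galnac1, Neu2, Neu4 and Ptprc.

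The tests were checked on simulated counts drawn from the means and totals of the real genes. Against 1 CPM, 50 of 50 genes at 2 CPM and 30 of 50 at 1.5 CPM were called above, 41 of 50 at 0.5 CPM and 18 of 50 at 0.667 CPM below, and 4 of 200 at exactly 1 CPM were called. For the ratio, all 1000 simulated genes at each of 0.5, 0.8, 1.25 and 2 times the reference were called in the right direction, and 131 of 4000 equal genes were called. For variation, 200 genes with a mean of at least 100 counts were given an added coefficient of variation of 0.5. Of these, 190 were found, with 17 false calls among 10801 others. That spread is far wider than the common value of 2.8% in the data, and smaller added variation was not simulated. Alternatives were other scalings (DESeq2 1.42.0 size factors, library totals), DESeq2's Wald test, other count minimums, levels of 0.5 and 2 CPM, an added count of 2, Ugcg as reference gene, counts per kilobase of exon, other sets of genes for the random lists, and each replicate left out in turn. An exact Poisson test of summed counts and a variation test on whole-count genes were chosen after seeing the data. Ranges of adjusted p over the alternatives set beforehand include the levels of 0.5 and 2 CPM, so their ends can belong to a level other than 1 CPM. Upper ends can also come from DESeq2's Wald test, which called no gene below 1 CPM.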

Results

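The data describe gene expression in B16 cells, a mouse melanoma line, that stably carry an empty expression vector (Mock). The series title concerns ST8Sia5, a sialyltransferase that extends gangliosides, its addition of sialic acid chains to itself and its release from cells. The empty-vector line is the background in which such an enzyme would be expressed, so the data address which sialyltransferases, ganglioside enzymes, possible carrier proteins and Golgi proteases these cells transcribe. RNA was measured by sequencing in 3 samples, Mock replicates 1, 2 and 3, which form a single group. No groups could therefore be compared. Each gene's level was instead set against 1 CPM (reads scaled to library size), against other genes of the same library, and between the 3 libraries. The libraries held 9328096, 9456527 and 9438905 counts, and 13424, 13178 and 13316 genes with at least 1 count in replicates 1, 2 and 3. A single read was thus worth about 0.106 CPM. The limit that no counts in any library allow is 3 counts over the group, or 0.106 CPM. Such limits cover counting error only. The labels do not say whether the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

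Of 18 sialyltransferase genes measured, 10 were transcribed above 1 CPM. They were all 6 members of the St3gal family, whose enzymes cap terminal galactose, St6gal1, and St6galnac3, St6galnac4 and St6galnac6. The most abundant was St3gal6 at 210 ± 10.04 CPM (mean ± SD, n = 3, as for all CPM values), followed by St3gal4 at 124 ± 4.73 CPM and St3gal5, the synthase of the ganglioside GM3, at 101 ± 1.53 CPM. St6galnac6 reached 65.3 ± 1.99 CPM, St3gal3 53.8 ± 2.06 CPM, St3gal2 51.2 ± 0.845 CPM, St6gal1 34.97 ± 0.966 CPM, St3gal1 34.0 ± 1.47 CPM, St6galnac4 32.4 ± 2.49 CPM and St6galnac3 3.44 ± 0.689 CPM. No member of the St8sia family, which builds chains of sialic acid on sialic acid, was above 1 CPM. St8sia5 itself (chromosome 18, 77185839 to 77258771, plus strand, GRCm38) had 1 read in replicate 1 and none in replicates 2 and 3, which is 0.0356 ± 0.0617 CPM. St8sia2, a polysialyltransferase of neural cells, likewise had 1 read in all, and St6galnac2 had 1 read in each library. These 3 genes were below 1 CPM by edgeR's quasi-likelihood F test, with an adjusted p of 6.10e-04 for St8sia5 and for St8sia2 and 6.05e-04 for St6galnac2. St8sia1, the GD3 synthase, and St8sia3, St8sia6 and St6galnac5 had no counts, which allows up to 0.106 CPM each. St8sia4, also a polysialyltransferase gene, was unresolved at 0.497 ± 0.376 CPM from 14 reads (edgeR adjusted p = 0.0666). Adjusted over the list alone, the counts were again 10 above and 3 below. DESeq2's Wald test called 0 genes of the table below 1 CPM, also at an unadjusted p under 0.05. It called none even among genes with 1 read, so it could not decide on these low genes. The same test left St6galnac3 without a call (adjusted p = 0.0752, range over the alternatives set beforehand 2.53e-08 to 0.0752). St8sia4 was called below 1 CPM when only genes with at least 10 counts were tested (edgeR adjusted p = 0.0309). The exact Poisson test of summed counts also called it below (adjusted p = 0.00515). Its range over the same alternatives was 0.002 to 0.984, where 0.002 is against 2 CPM. Here and below, such ranges include tests against 0.5 and 2 CPM, so an end need not refer to 1 CPM. They also include DESeq2's Wald test, which gives the upper end for the genes called below 1 CPM whose ranges follow. St6gal2 and St6galnac1 were not analysed here.

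**Figure D1:**
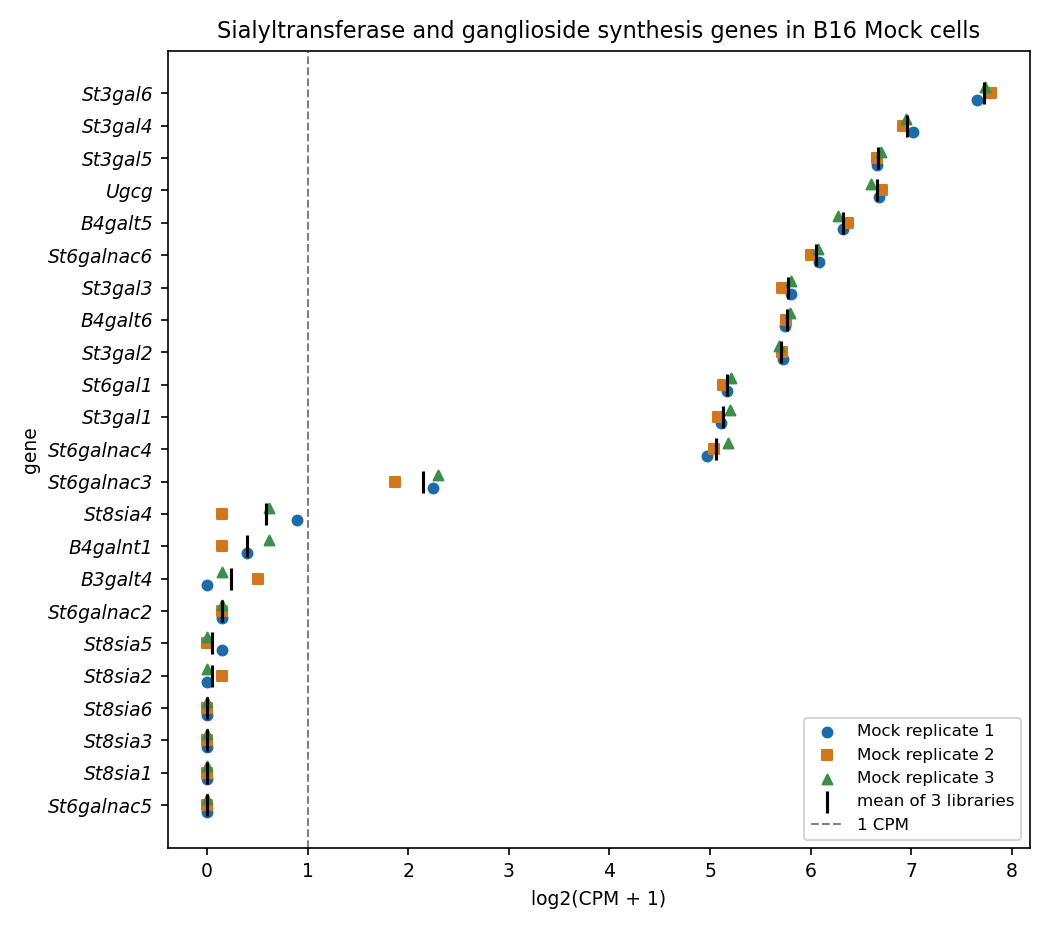
Expression of sialyltransferase and ganglioside synthesis genes in the 3 Mock libraries, on a log2(CPM + 1) axis with 1 gene per row. Coloured symbols are single libraries, black bars the means of the 3 libraries and the dashed line 1 CPM. St3gal6 leads at a mean of 210 CPM, and the St8sia genes lie to the left of the line.

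Within each library, St3gal6 (chromosome 16, 58468125 to 58524243, minus strand) had more reads than St3gal5 (chromosome 6, 72097592 to 72154571, plus strand), and St3gal4 had slightly more. The log2 ratio to St3gal5 was 1.06 ± 0.07 for St3gal6 (SD, n = 3) and 0.29 ± 0.06 for St3gal4. The other 11 sialyltransferase genes with a count lay below St3gal5 by limma on the log2 ratios. The gap was moderate for St6galnac6 (-0.63 ± 0.04), St3gal3 (-0.91 ± 0.05), St3gal2 (-0.98 ± 0.05), St6gal1 (-1.53 ± 0.02), St3gal1 (-1.57 ± 0.04) and St6galnac4 (-1.64 ± 0.09). It was wide for St6galnac3 (-4.87 ± 0.29) and St8sia4 (-7.85 ± 1.30). The single reads of St8sia5 and of St8sia2 each equal 0.0352% of the 2845 St3gal5 reads, with an exact 95% interval of 0.000890% to 0.196%, and the 3 reads of St6galnac2 equal 0.105% (0.0217% to 0.309%). St8sia1, St8sia3, St8sia6 and St6galnac5 were at least 948-fold lower than St3gal5, with the floor of 3 counts taken over the group. The adjusted p of the St3gal6 ratio was 1.89e-36 and that of the St3gal4 ratio 1.83e-11 (limma), both higher in 3 of 3 libraries. Gene length enters these ratios: per kilobase of annotated exon, St3gal6 fell below St3gal5, at a log2 ratio of -0.18, and St3gal4 stood at 0.13. The moderate gaps widened to -1.50 for St6galnac6, -0.99 for St3gal3, -1.92 for St3gal2, -2.44 for St6gal1, -2.96 for St3gal1 and -2.95 for St6galnac4.

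The route from ceramide to GM3 was transcribed throughout, while the genes that extend GM3 were scarce. Of 13 ganglioside synthesis genes, 8 were above 1 CPM, 3 below and 2 without counts, and the split was the same adjusted over the list alone. Ugcg, which makes glucosylceramide, reached 100.3 ± 3.70 CPM. The lactosylceramide synthases B4galt5 and B4galt6 reached 79.2 ± 2.79 and 53.4 ± 1.11 CPM. Ugcg was not distinguishable from St3gal5 in the same libraries, at a log2 ratio of -0.01 ± 0.07 (limma adjusted p = 0.848), whereas B4galt5 lay at -0.35 ± 0.07 and B4galt6 at -0.92 ± 0.01. Per kilobase of annotated exon these ratios were -1.0 for Ugcg, -1.07 for B4galt5 and -2.07 for B4galt6, so the near equality of Ugcg and St3gal5 holds for reads only. B4galnt1 (chromosome 10, 127165225 to 127172330), which starts the GM2 branch, had 9 reads in the 3 libraries, or 0.319 ± 0.212 CPM. B3galt4, which makes GM1 from GM2, had 5 reads, or 0.177 ± 0.221 CPM. Both were below 1 CPM by edgeR (adjusted p = 0.00909 and 0.00579), together with St8sia5. St8sia1 and St6galnac5 had no counts. The later sialyltransferases of the pathway, St3gal1, St3gal2, St6galnac6 and St6galnac3, were among those above 1 CPM. Without replicate 1, B4galnt1 and B3galt4 were unresolved (adjusted p = 0.103 and 0.0629), and so was B3galt4 without replicate 3 (0.0886). The ranges over the alternatives set beforehand were 3.69e-04 to 0.592 for B4galnt1 and 4.65e-04 to 0.411 for B3galt4. Both upper ends are from DESeq2's Wald test, which called no gene of the table below 1 CPM.

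Ceramide synthesis genes upstream of this route were also transcribed. Of 15 other glycosphingolipid synthesis genes, 10 were above 1 CPM, led by Sptlc2 of serine palmitoyltransferase at 329 ± 12.4 CPM, the ceramide synthase gene Cers2 at 224 ± 12.2 CPM, the desaturase gene Degs1 at 182 ± 2.07 CPM and Cers5 at 117 ± 6.02 CPM. Genes of other glycolipid series were scarce: A4galt and Gbgt1 were below 1 CPM, and B3gnt5, B3galnt1 and Gal3st1 had no counts. All 7 sialic acid supply genes measured were above 1 CPM. Nans reached 121 ± 5.04 CPM, Cmas, which activates sialic acid to its CMP form, 71.5 ± 3.06 CPM, Gne 65.2 ± 3.91 CPM and the Golgi CMP-sialic acid transporter gene Slc35a1 34.7 ± 2.30 CPM. Of the sialidases, Neu1 stood at 86.8 ± 2.70 CPM and Neu3 at 3.69 ± 0.787 CPM, and both were above 1 CPM. Degradation genes had the highest median of these lists, at 79.2 CPM. All 15 genes of that list, which holds Neu1 and Neu3 as well, were above 1 CPM, led by the saposin precursor Psap at 1044.1 ± 18.04 CPM, Ctsa at 492 ± 7.32 CPM, Hexa at 383 ± 11.1 CPM and Asah1 at 137 ± 2.76 CPM. Counts above and below were the same for each of these 4 lists adjusted over the list alone. Among 10000 random gene lists of the same size, the list medians stood at percentile 47.9 for sialyltransferases, 87.7 for ganglioside synthesis, 75.2 for other glycosphingolipid synthesis, 81.1 for sialic acid supply, 69.0 for sialidases and 99.8 for degradation. The percentile of sialyltransferases was 75.8 per kilobase of exon. It was 1.1 when random lists were drawn only from genes with at least 10 counts. The list kept its own members with fewer counts there, which such random lists cannot hold. The 1.1 is therefore not a like comparison and does not rank the list.

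Transcripts of proteins known to carry polysialic acid were present. Of 6 carriers, 4 were above 1 CPM: Nrp2 at 411 ± 5.79 CPM, Glg1 (the E-selectin ligand ESL-1) at 75.4 ± 2.63 CPM, the neural cell adhesion molecule gene Ncam1 at 60.9 ± 5.50 CPM and Cadm1 at 13.6 ± 0.242 CPM. Cd36 was below 1 CPM with 1 read, and Ccr7 had no counts. All 19 genes of Golgi proteases and retention factors were above 1 CPM. The retention factor Golph3 reached 300.2 ± 5.62 CPM, the sheddase Adam10 108 ± 0.827 CPM, the Golgi matrix gene Golga2 90.7 ± 3.65 CPM and the intramembrane protease gene Sppl2b 90.6 ± 1.78 CPM. Sppl3, whose protease releases Golgi glycosyltransferases, stood at 49.3 ± 1.44 CPM, and Bace1, whose protease cleaves St6gal1 protein, at 19.9 ± 0.892 CPM. These last 2 genes were singled out after their values were seen. Adjusted over the list alone, all 19 and the 4 carriers were again above. The list medians stood at percentile 77.5 for carriers and 99.3 for Golgi genes. The percentile of Golgi proteases and retention was 90.6 against lists drawn from genes with at least 10 counts.

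Pigment cell transcripts were among the most abundant. Tyrp1, a melanosomal enzyme, was the most abundant gene of the table at 12337.4 ± 399 CPM. The melanosomal glycoprotein gene Gpnmb followed at 5829.9 ± 190 CPM, Dct at 2713.0 ± 47.7 CPM and Pmel at 1257.6 ± 66.6 CPM. Of 20 pigment cell genes 18 were above 1 CPM, and the list median stood at percentile 100. Tyr, the rate-limiting enzyme of melanin synthesis, was far lower at 6.52 ± 0.839 CPM, while the receptor gene Kit was below 1 CPM with 6 reads and Ednrb had no counts. The values of Tyr and Kit were singled out after they were seen, and Kit had no call at 0.5 CPM (edgeR adjusted p = 0.0552, range over the alternatives set beforehand 1.23e-04 to 0.462). Besides Tyrp1, Gpnmb and Dct, the 20 most abundant genes included the glycolytic genes Gapdh and Eno1, the translation genes Eef1a1, Eef2, Rps2 and Pabpc1, the ferritin genes Ftl1 and Fth1, the chaperone genes Hsp90ab1, Hspa8 and Ppia, and Atp5b, Ctsd, Tuba1b, Gm39701 and Gm40498. Together the top 20 held 8.9% of the counts in each library. Gm39701 (8344.9 ± 652 CPM) and Gm40498 (2582.6 ± 95.3 CPM) are gene models without a matched annotation and with fractional counts, so their levels are uncertain.

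Cell cycle genes were abundant, with 18 of 20 above 1 CPM. The replication genes Top2a and Pcna reached 455 ± 16.3 and 447 ± 11.3 CPM, the proliferation marker Mki67 436 ± 21.9 CPM and the cyclin gene Ccnd1 362 ± 18.2 CPM. The exceptions were the neighbouring inhibitor genes of the INK4 locus: Cdkn2a had no counts and Cdkn2b a single read, the latter below 1 CPM. All 14 reference genes were above 1 CPM, led by Gapdh at 10468.5 ± 73.5, Ppia at 2484.0 ± 33.4, Actb at 2276.8 ± 55.3 and Pgk1 at 1439.9 ± 18.05 CPM. Both lists stood at percentile 100, and their counts did not change adjusted over the list alone.

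Antigen presentation genes were split. The light chain gene B2m stood at 391 ± 4.02 CPM, the tapasin gene Tapbp at 81.1 ± 3.24 CPM, Psmb10 at 17.2 ± 2.44 CPM, the class I transactivator gene Nlrc5 at 2.34 ± 0.556 CPM and Cd74 at 1.63 ± 0.429 CPM, and these 5 of 12 genes were above 1 CPM. The classical class I heavy chain genes H2-K1 and H2-D1 had 6 and 9 reads in all, the peptide transporter gene Tap1 and the class II transactivator gene Ciita 1 read each, and these 4 were below 1 CPM. The immunoproteasome genes Psmb8 and Psmb9 had no counts. Tap2 was unresolved at 1.06 ± 0.460 CPM. The list median stood at percentile 9.9, and the counts were the same adjusted over the list alone. H2-K1 was unresolved without replicate 1 or 3 (edgeR adjusted p = 0.051 and 0.0894, range over the alternatives set beforehand 5.00e-04 to 0.462), H2-D1 without replicate 2 or 3 (0.0515 and 0.0615, range 2.58e-04 to 0.592) and Cd74 without replicate 1 or 2 (0.144 and 0.137, range 2.54e-04 to 0.706). H2-D1 had fractional counts, so its level is uncertain, and DESeq2's Wald test left Nlrc5 and Cd74 without a call (adjusted p = 0.368 and 0.706).

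Markers of other cell types were mostly at or near the floor. Of 11 leukocyte markers 2 were above 1 CPM, Cd68 at 812 ± 21.2 CPM, which encodes a lysosomal membrane protein, and Fcer1g at 4.32 ± 0.636 CPM. Cd8a, Laptm5 and Cd79a were below, and Cd4, Cd3g, Csf1r, Adgre1, Tyrobp and Ly6g had no counts. Of 9 fibroblast markers, Col1a2 (27.6 ± 1.39 CPM), Col1a1 (8.29 ± 1.63 CPM), Pdgfrb (3.33 ± 0.421 CPM) and Postn (3.22 ± 0.408 CPM) were above. Pdgfra was below, and Dcn, Col3a1, Thy1 and Fap had no counts. Of 9 endothelial markers only Egfl7 was above, at 11.9 ± 0.436 CPM. Vwf, Pecam1, Tek and Esam were below, and Tie1, Kdr, Cdh5 and Emcn had no counts. Of 8 neuronal markers Tubb3 (79.9 ± 0.473 CPM) and Map2 (26.9 ± 3.10 CPM) were above, Slc17a7 was below, and Snap25, Syt1, Gad1, Nefl and Stmn2 had no counts. Of 8 epithelial markers Krt8 (5.04 ± 4.41 CPM) and Krt18 (3.30 ± 2.98 CPM) were above, Krt19 (2.02 ± 1.66 CPM) and Cdh1 (1.17 ± 0.284 CPM) were unresolved, Cldn4 and Cldn7 were below, and Krt14 and Esrp1 had no counts. The values of Krt8 and Krt18 rested mainly on replicate 1: without it Krt8 and Krt18 were unresolved (edgeR adjusted p = 0.105 and 0.369, ranges over the alternatives set beforehand 9.53e-07 to 0.105 and 9.26e-05 to 0.369), and Krt18 was unresolved without replicate 3 as well (0.11). Krt19 depended on the processing: it was called above 1 CPM without replicate 2 (0.0236), with library totals (0.0329) and among genes with at least 10 counts (0.00892), and its log2 distance of 1.01 ran from 0.22 to 1.5 with each replicate left out. Because the extraction text of the labels mentions organs, 11 organ markers were measured as well. None was above 1 CPM by edgeR: 10 were below, among them Hba-a1 with 8 reads, Myh7 and Nphs1 with 4 each and Acta1 with 3, and Scgb1a1 had no counts. List medians stood at percentile 0.0 for leukocyte and neuronal, 7.2 for fibroblast, 4.2 for endothelial, 10.7 for epithelial and 2.2 for organ markers, and the counts above and below were the same adjusted over each list alone. Cd8a, Laptm5, Cd79a, Pdgfra, Vwf and the organ markers Myh7 and Apoa1 each lost the call without at least 1 replicate (edgeR adjusted p between 0.051 and 0.176). DESeq2's Wald test left Pdgfrb, Postn and Krt18 without a call.

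**Figure D2:**
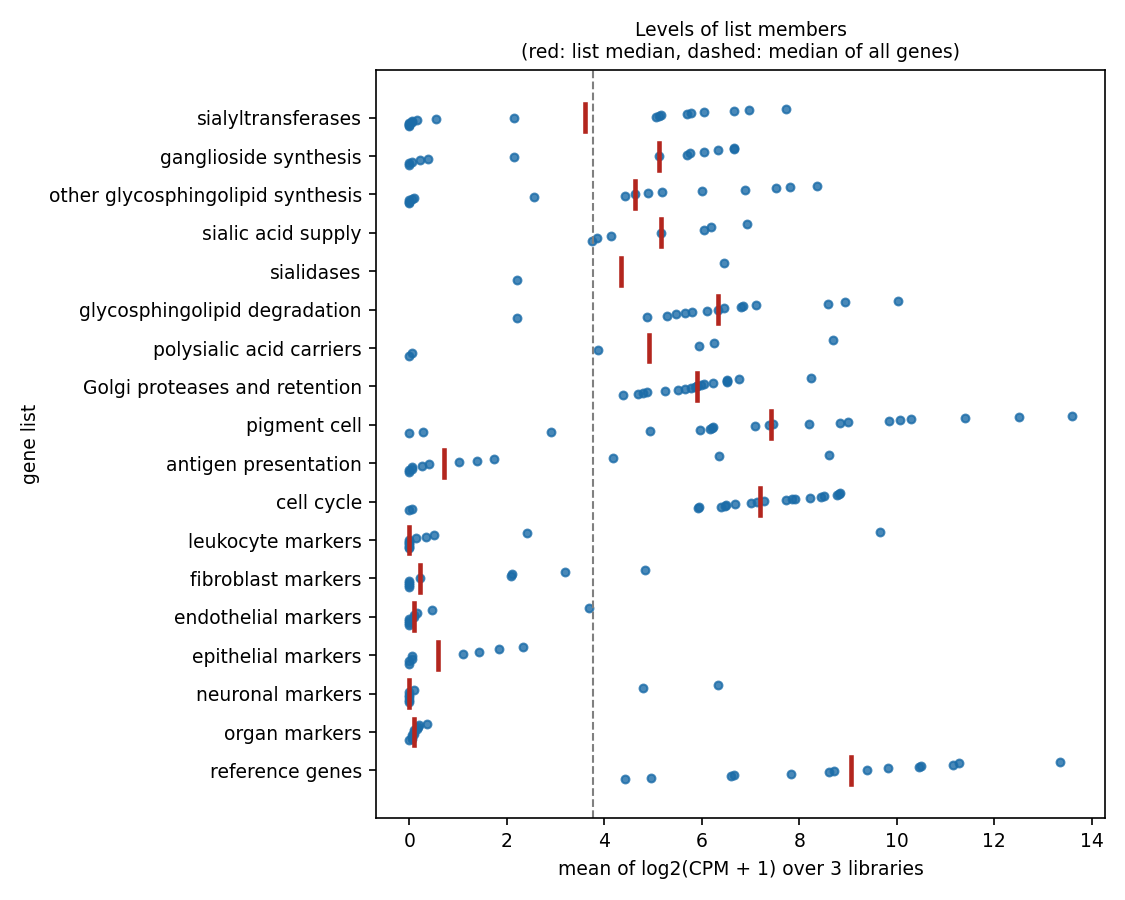
Levels of the members of 18 gene lists, as the mean over 3 libraries of log2(CPM + 1), with 1 point per gene and 1 row per list. Red bars are list medians and the dashed line is the median of all genes of the table. Pigment cell, cell cycle and reference genes stand at percentile 100 of random lists, and leukocyte and neuronal markers at 0.0.

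Across the table, 10711 of 14408 genes with a count were above 1 CPM, 2907 were below and 790 were unresolved (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). A further 2877 genes had no count after rounding. The number above 1 CPM ranged from 10091 to 10779 over the alternatives that kept this level, and 11125 genes were above a level of 0.5 CPM. The number below was less stable, at 1835 without replicate 1. DESeq2's Wald test called 0, also at an unadjusted p under 0.05. Because it called none even among genes with 1 read, its 0 does not measure how stable that number is.

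The 3 libraries were close to one another but not interchangeable. Of 11000 genes with a mean of at least 10 counts, 364 (3.3%) varied between the libraries beyond counting noise, and the common biological coefficient of variation was 2.8%. Among such genes with a mean of at least 100 counts, the widest ranges belonged to gene models and to Atat1, the tubulin acetyltransferase gene. Gm14308 had 209, 53 and 85 reads in replicates 1, 2 and 3, a log2 range of 1.82, followed by Gm4724 (1.20), LOC100862468 (0.89), Gm14434 (0.77) and Atat1 (0.73). All 5 had fractional counts, so their levels are uncertain. The narrowest ranges that still passed were those of abundant genes: Actb and Eef2 at 0.06, and Pkm, Dct and Hsp90ab1 at 0.05. Most of these calls were lost when 1 replicate was left out. The range of Gm14308 fell to 0.60 and that of LOC100862468 to 0.01 without replicate 1, that of Gm14434 to 0.04 without replicate 2, and that of Atat1 to 0.59 without replicate 2 and 0.14 without replicate 3. None of these passed, and the 5 narrowest each also lost the call without at least 1 replicate, whereas Gm4724 kept it. None of the 10 sialyltransferases with a mean of at least 10 counts passed this test, and the lowest adjusted p among them was 0.157, for St3gal6. Among the most abundant genes, the chaperone gene Hspa8 (log2 range 0.26) and Tyrp1 (0.09) did vary. Summed over genes, the deviance per degree of freedom was 1.86 between replicates 1 and 2, 2.0 between 1 and 3 and 1.64 between 2 and 3, where counting noise alone gives about 1. The median over genes, for all 3 libraries, was 1.02 where counting noise alone gives 0.69, so the typical gene exceeded it by less than the mean did. Every pair differed beyond sampling noise, so no 2 samples were counted as 1 library. Across genes, which are not independent replicates, log2 values of the pairs correlated at r = 0.995. The Poisson deviance test compares these libraries, not conditions. It called 129 genes without replicate 1, 244 without replicate 2 and 175 without replicate 3, and 239 among genes with whole counts in every sample.

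**Figure D3:**
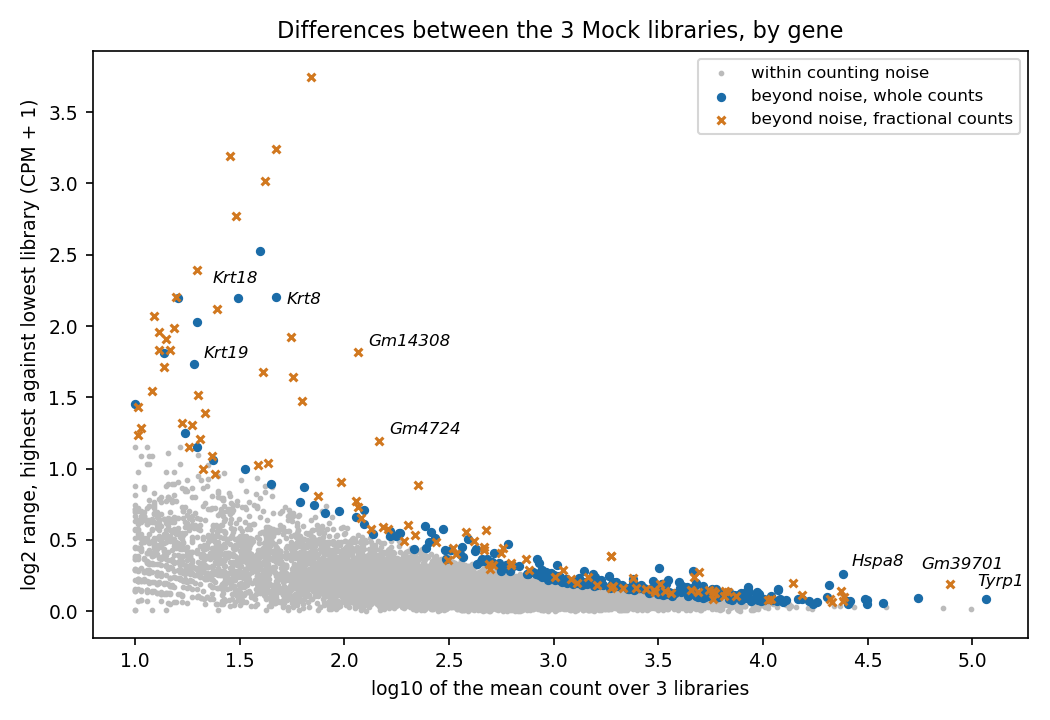
Range between the 3 Mock libraries (log2 of CPM + 1, highest against lowest) plotted against the log10 mean count for 11000 genes. Grey points, labelled as within counting noise, are genes that did not pass the variation test. Blue points are varying genes with whole counts and orange crosses varying genes with fractional counts. Ranges narrow as counts grow: Gm14308 spans 1.82, whereas Tyrp1 spans 0.09.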

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

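The exact Poisson test of summed counts and the restriction to whole-count genes were chosen after the data had been examined; the other alternatives were set before. With 1 CPM as the level, the number of genes above it stayed between 10091 and 10779, and 11125 and 10321 genes were above levels of 0.5 and 2 CPM. Over all alternatives, sialyltransferases above the tested level numbered 9 to 10, ganglioside synthesis genes above it 7 to 8 and sialyltransferases below St3gal5 8 to 11. The number of genes below 1 CPM (2907) was the least stable. DESeq2's Wald test called 0, also at an unadjusted p under 0.05, and the cause was not tested. It gave an adjusted p of 0.141 even to St8sia5 with 1 read, the fewest tested, where the exact Poisson test gave 4.12e-11. Its 0 therefore does not measure how stable the number is. The exact Poisson test called 3024. Testing only genes with at least 10 counts gave 408, since most low genes were then left out, and testing all genes gave 5786, since genes with no count then entered. Leaving out each replicate in turn gave 1835 to 2203. Varying genes (364) numbered 129 to 244 with each replicate left out. Fewer samples entered there, but the number also depended on which replicate was dropped. With whole counts only there were 239. Fewer genes entered, and in the main test a smaller share of whole-count genes varied (2.8%) than of genes with fractional values (6.1%). The common coefficient of variation of 2.8% ranged from 2.46% to 3.16% with each replicate left out. Lists at or above percentile 97.5 numbered 4 to 5.

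Some named genes near the tested level changed side. With 0.5 CPM as the level, log2 distances turned positive for Sox9 (0.94), Ctgf (0.83), H2-T24 (0.94), Oas1a (0.43), Usp18 (0.64), Itgb3 (0.64) and Itgb8 (0.18). With 2 CPM they turned negative for Tap2 (-0.91), Cd74 (-0.30), Cdh1 (-0.77), H2-T10 (-0.39), Krt7 (-0.12) and Krt20 (-0.91). In both settings the level itself moved past the gene. With each replicate left out, the sign also changed for 5 unresolved genes, Krt20 (-0.78 to 0.63), Tap2 (-0.32 to 0.29), Sox9 (-0.54 to 0.16), H2-T24 (-0.24 to 0.23) and Ctgf (-0.43 to 0.02), and the cause was not tested. Per kilobase of exon, St3gal6 stood at -0.18 relative to St3gal5, since its annotated exons are longer. Among results for single genes, DESeq2's Wald test ended 59 calls, among them every call below 1 CPM. Leaving out replicates 1, 2 and 3 ended 20, 10 and 17. Levels of 0.5 and 2 CPM ended 15 and 3 calls of genes that kept their side. The level of 2 CPM also ended the calls of Cd74 and Krt7, which changed side (edgeR adjusted p = 0.239 and 0.739). Depth limits the low genes: St8sia5 rested on 1 read and B4galnt1 on 9. No paired analysis was possible because the labels give a single group.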

Other observations

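The gene lists and tests of this part were chosen after the table had been examined; the added lists were written before the values of their genes were looked up, except genes already described in the report. Stress and chaperone genes were strongly transcribed. Of 16 heat shock genes 14 were above 1 CPM, led by Hsp90ab1 (3349.4 ± 60.6 CPM), Hspa8 (2564.1 ± 243 CPM) and Hspd1 (1074.7 ± 24.4 CPM), whereas Hspb1 had no reads. The inducible genes Hspa1a and Hspa1b, near-identical copies, had 4 and 241 reads, and as both have fractional counts, the split between them is uncertain. Of 12 endoplasmic reticulum stress genes 11 were above, among them the chaperone gene Hspa5 (1169.8 ± 33.0 CPM), the transcription factor gene Atf4 (978 ± 15.7 CPM) and its target Asns (964 ± 18.02 CPM), with Atf3 at 1 read. All 20 MAPK and PI3K pathway genes were above, including the ERK-responsive genes Dusp6 (350.2 ± 25.0 CPM), Etv5 (266 ± 4.48 CPM) and Etv4 (108 ± 3.46 CPM). The 3 lists stood at percentile 100 of random lists.

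Genes of the enzymes that build glycoprotein acceptors of sialic acid were transcribed. All 12 N-glycan branching genes were above 1 CPM (percentile 98.1), led by Mgat4b (314 ± 10.8 CPM) and Mgat2 (92.9 ± 5.17 CPM), and 7 of 12 O-glycan core genes were (percentile 68.6), led by Galnt2 and Galnt1 (122 ± 3.44 and 121.5 ± 2.04 CPM). Of 14 integrin genes 11 were above (percentile 56.7), led by Itgb1 (319 ± 2.50 CPM) and Itga6 (175 ± 1.97 CPM). Of 15 genes of invasive or dedifferentiated melanoma 8 were above (percentile 30.1), led by Cdh2 (392 ± 4.86 CPM), Fn1 (146 ± 1.97 CPM) and Axl (78.3 ± 1.03 CPM), while Ngfr, Egfr, Tnc and Zeb1 were below 1 CPM and Wnt5a had no counts. Of 19 interferon pathway genes 15 were above (percentile 49.8). The receptor and kinase genes Ifnar1 (102 ± 2.59 CPM) and Jak1 (168 ± 9.35 CPM) were among them, but Isg15 stood at 2.87 ± 0.556 CPM, without a call by DESeq2's Wald test (adjusted p = 0.189), and Irf7 at 2 reads. Of 8 keratin genes 4 were above (percentile 19.3), or 3 adjusted over the list alone, led by Krt80 at 151 ± 5.90 CPM. Krt7 lost its call without replicate 1 or 3 (edgeR adjusted p = 0.534 and 0.267) and by DESeq2's Wald test (0.604). Tnc lost its call without replicate 1 (edgeR adjusted p = 0.051), and Zeb1 lost its call without replicate 2 or 3 (edgeR adjusted p = 0.0874 and 0.0886).

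Reads of some keratin genes differed between the libraries together. Krt8, Krt18 and Krt19 summed to 189, 23 and 80 reads in replicates 1, 2 and 3, a scaled ratio of replicate 1 to 2 of 8.28, for which depth does not account, since the library totals differed by a ratio of at most 1.014. Reads or cells of 1 keratin-rich source in unequal amounts stay open: of the 3 other listed keratins with a mean of at least 10 counts, permutation tests of 100000 resamples found no departure from that split for 2, Krt7 (p = 0.21) and Krt20 (p = 0.611), but did for Krt80, the most abundant, at 1347, 1463 and 1441 reads (p = 1e-05). Transcription of Krt80 in the B16 cells themselves would hide a small share from another source, and the epithelial genes Cldn4 and Cldn7 had 1 read each, while Cdh1 (33 reads) did not pass the variation test (adjusted p = 0.805). Other cells and keratin-transcribing B16 cells were not told apart, and no biological explanation was tested, since the design gives a single group.

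Whole-count varying genes with means of 10 to 100 counts partly followed the order of these genes. Of 18 such genes 10 were highest in replicate 1 and lowest in replicate 2, but 5 of these are keratins, from which the order was taken. Without the keratins it was 5 of 13, where 2.2 are expected by chance, and these included S100a6 (73, 5 and 40 reads), Cd24a (38, 1 and 9), Ly6e (37, 2 and 20) and Cav1 (27, 1 and 13). Above 100 counts, 22 of 239 had that order, against 39.8 expected.

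Variation between the libraries was more frequent among genes whose reads are shared. Fractional values occurred in 29.4% of varying and 15.6% of other genes. The odds ratio was 2.25 (95% interval 1.77 to 2.85, p = 8.56e-11 by Fisher's exact test). That test treats genes as independent, but genes that share reads can vary together, so the interval is too narrow and the p too small. Reads divided between near-identical genes remain a candidate source of part of the variation. They cannot be its whole cause: 239 genes with whole counts varied when tested on their own, against 17 false calls among 10801 genes without added variation in a simulation of 11001 genes. No biological explanation was tested. In the protocadherin gamma cluster (chromosome 18, 37661793 to 37841873), whose genes share exons, 12 of 22 genes varied and 11 had no reads in one library and reads in another, and the cluster's sum of 1103, 959 and 990 reads also differed beyond counting noise by the Poisson deviance test.

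Transcripts of 5 class I pathway genes were scarce while those of B2m, Tapbp and Psmb10 were not, and the calls of H2-K1 and H2-D1 were lost when some replicates were left out. Reads shared between near-identical genes were weighed by the share of each gene's 31-base words found in no other gene, 95.9% for Tap1, 86.3% for Psmb8, 95.2% for Psmb9, 77.2% for H2-K1 and 73.1% for H2-D1. If reads fall evenly over these words, at least that share of a gene's reads stays with it. The upper 95% limits then rise to at most 0.206 CPM for Tap1, Psmb8 and Psmb9 and 0.828 CPM for H2-K1 and H2-D1. On that assumption shared reads do not bring any of the 5 genes to 1 CPM. The words were pooled over all GENCODE transcripts of a gene, and the annotation behind the counts is not given. Uneven coverage, isoform use and copies outside GENCODE were not tested. They would matter most for H2-D1, whose counts are fractional. Of 13 class I heavy chain genes 4 were above 1 CPM (percentile 7.8), led by H2-T22 at 30.7 ± 2.36 CPM, whose counts are fractional, and the 11 other than H2-K1 and H2-D1 summed to 53.2 ± 3.38 CPM, against 391 CPM for B2m.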
